A study of Homo sapiens with 12 samples.

How the data were processed

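RNA was sequenced from RPMI2650 cells, a human nasal epithelial line, in 3 groups of 4 libraries: control, 1 µM PFBA and 1 µM PFHxA, each acid for 7 days at an air-liquid interface. Per the labels, libraries were made from total RNA with a VAHTS Universal kit and run on an Illumina NovaSeq instrument. The labels do not say whether the 4 libraries of a group come from separate cultures, so that they may be technical replicates. The deposited table holds raw read counts per Ensembl gene, 1 column of counts per library, made by the authors from alignments with HISAT2 2.0.4 to the human genome (GRCh38, hg38) according to the submitters' processing notes. The program that counted the reads, the annotation release and the strand setting are not given in the sources used here. The 12 columns of FPKM in the same table were not used, since the counts of the same libraries were tested. Column prefixes were read as PFBA, PFHxA and control. The letters a to d within a group are those of the columns and are not tied to the numbers in the labels, so that libraries are named by group and letter.

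Gene positions are those of the table. GC content and length were taken from the longest transcript of each gene in GENCODE 29, which holds 50111 of the 50868 gene identifiers, 94.8% of them at the same position and 99.9% at an overlapping one. Mitochondrial shares of single libraries carry a Wilson interval at 95%, which covers counting error only, since reads without molecular identifiers are not independent molecules.

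The fits were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. Genes were kept by filterByExpr on the groups with its default minimum count of 10 and total of 15, libraries were scaled by TMM factors, and all 12 libraries entered 1 edgeR quasi-likelihood fit with robust dispersion and group as the only term. Each of the 3 pairs of groups was compared by a two-sided F test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F, and intervals are at 95%. CPM uses the TMM-scaled totals, and log2 CPM adds a prior count of 2. A single measure compared between 4 and 4 libraries was given an exact permutation test, two-sided, whose smallest p is 0.0286.

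Gene lists were fixed in 41 groups before the data were examined, as were the tests, the rule for named genes and the alternatives named below unless said otherwise. Of these, 38 had at least 5 tested members and were tested by camera (limma) on log2 CPM with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38. No call, with or without the GC and length trend removed, held with an estimated correlation between genes in any of the 3 comparisons, whose counts of lists called were 8, 11 and 3 with the preset one. Each list also has the number of members called over all genes and the number called when adjusted over the list alone. The lists cover stress responses, lipid and nuclear receptor targets, cell cycle, interferon and inflammatory genes, airway and other cell types, junctions, matrix and signalling targets, mitochondria, lysosome, apoptosis, carriers, ribosomes, histones and small RNAs.

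Named genes were chosen by rule. In each comparison these are the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM, no overlap between the 4 libraries of each group and a symbol that is not a clone, pseudogene or small RNA name. Where a direction had none, the 5 genes with the smallest p were taken. To these were added up to 4 genes with the smallest p of each list that passed or held at least 2 calls. Genes named in 1 comparison may be given in the others. Y-linked genes and XIST were left out, and some genes that meet these rules are not reported here.

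The alternatives were RLE and upper-quartile scaling, no filter, a stricter filter (at least 1 CPM in 4 libraries and a mean count of 50), a fit of the 8 libraries compared, limma-voom, DESeq2, a minimum change of 1.5-fold, an estimated correlation in camera, and leaving out each library in turn. Alternatives chosen after the data were seen were the removal of each library's trend over GC content and log2 transcript length (natural splines with 5 degrees of freedom each, fitted to the library's deviation from the gene mean and given to edgeR as offsets) and thinning of every library to the smallest total. A further fit also removed trends over the shares of 200-nt windows under 35% and over 65% GC (splines with 3 degrees of freedom). A block for replicate number was planned and could not be fitted, as the columns carry no label numbers, and a block for the column letter was fitted instead.

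For the response shared by both acids, 20 tables were simulated with the control means and fitted dispersions and no change in any group, and the controls were split into 2 and 2 in all 6 ways. The fit was tested on simulated data with 50 genes changed at each of 4 sizes in 16554: 24% were recovered at 1.25-fold, 50% at 1.5-fold, 84% at 2-fold and 100% at 4-fold, 8 of 137 calls were false, and 0 genes were called in a comparison with no change. A list shifted by 0.3 on the log2 scale had an adjusted p of 6.11e-23 with 0 other lists called, and 1 list was called in the comparison with no change. Genes were drawn independently in this simulation, so that it does not test the preset correlation. The correlation estimated from the libraries was 0.217 for nuclear-encoded oxidative phosphorylation, 0.328 for cytosolic ribosomal proteins and 0.883 for mitochondrially encoded genes. To look for duplicated libraries, pairs were compared over genes by chi-square per degree of freedom, which ran from 11.1 to 24.3 within groups and from 12.7 to 41.1 between groups.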

Results

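Gene-level read counts were analysed from 12 RNA-seq libraries of RPMI2650, a human epithelial cell line derived from a tumour of the nasal septum, grown at an air-liquid interface. The groups were 4 control libraries, 4 libraries after 7 days with 1 µM perfluorobutanoic acid (PFBA) and 4 libraries after 7 days with 1 µM perfluorohexanoic acid (PFHxA). Both are perfluoroalkyl carboxylic acids, and PFHxA has the longer chain. No day is recorded for the control libraries, whose treatment label is Control alone. A match of the controls in culture time or vehicle can therefore not be checked here. The total count per library ran from 16941599 in control d to 21879105 in PFBA a, with a mean of 19208600 in control, 20304400 with PFBA and 18994100 with PFHxA. Of 50868 genes in the table, 16554 had enough counts to be tested. The biological coefficient of variation of the fit was 0.127. Levels are given as CPM, the count scaled to the effective size of the library, as mean ± SD with n = 4 in each group, genome positions are on GRCh38, and an adjusted p for a gene is from edgeR over all 16554 genes.

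The most abundant transcript was MT-CO1, with 3.12% of all counts. Mitochondrial genes together took 10.9% ± 1.253 of the counts in control, 11.4% ± 0.239 with PFBA and 12.6% ± 0.575 with PFHxA. Control d held the lowest share, 9.15% (95% Wilson interval 9.13 to 9.16, which covers counting error only). The share was higher with PFHxA than with PFBA in all 4 libraries against all 4 (exact permutation test, two-sided, p = 0.0286, the smallest p that 4 against 4 allows; adjusted p = 0.137 over 24 tests of library measures), and the difference from control had an exact p of 0.0571. The libraries also differed in how gene levels followed the GC content of the transcript. The slope per 10 points of GC was -0.0405 ± 0.0238 on the log2 scale in control, between -0.0650 and 0.00417 in the 4 PFBA libraries and between 0.0706 and 0.104 in the 4 PFHxA libraries, so that PFHxA stood apart from both other groups (exact permutation p = 0.0286 for each, adjusted p = 0.137). The slope per doubling of transcript length was also higher with PFHxA (0.0194 ± 0.00514) than in control (-0.0273 ± 0.0244; exact permutation p = 0.0286, adjusted p = 0.137), and it was not separated from that with PFBA (0.00787 ± 0.0223, exact p = 0.371). No batch, date or lane is given for any library, so that these measures and the PFHxA group cannot be separated by a blocked fit.

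**Figure D1:**
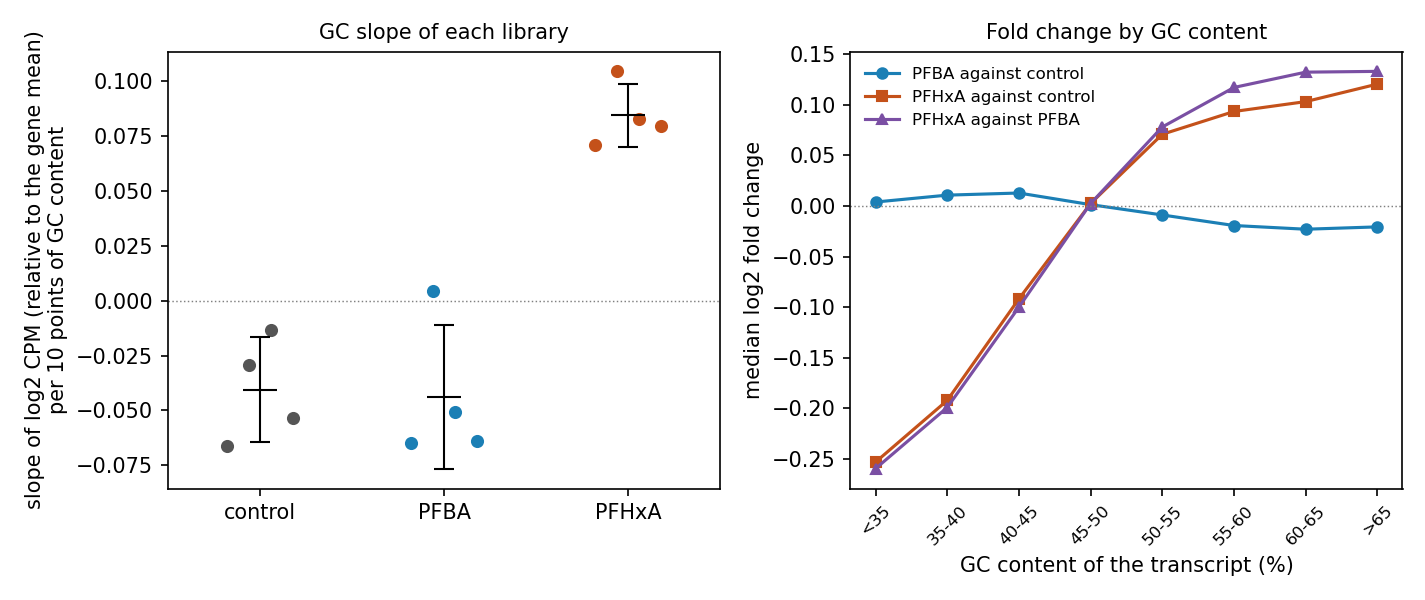
Left, slope of log2 gene level on transcript GC content (log2 units per 10 percentage points) in each of the 12 libraries by group, with bars for mean and SD (n = 4). Right, median log2 fold change of the genes in bins of GC content for the 3 comparisons. The 4 PFHxA libraries lie between 0.0706 and 0.104, above all other libraries.

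The comparison of PFBA with control asked what the shorter acid changed. Of 16554 genes, 1 passed the test. Genes of oxidative phosphorylation encoded in the nucleus were lower with PFBA as a list: 53 of 56 members had a lower fitted level and the mean log2 fold was -0.17 (camera adjusted p = 3.46e-19, adjusted p = 0.191 with an estimated correlation). None of these 56 passed over all genes, and 19 were lower when adjusted over the list alone. Among them, NDUFA2 of complex I was at 46.1 ± 2.18 CPM with PFBA and 56.6 ± 3.75 CPM in control (adjusted p = 0.256), and ATP5MC3 of the ATP synthase was at 282.4 ± 3.20 and 326.3 ± 14.3 CPM (adjusted p = 0.256). Control d, the library with the lowest mitochondrial share, had the highest mean of this list among the controls, 0.13 on the log2 scale above the control mean, where the others lay between -0.07 and 0.01, and PFBA d was also at -0.07.

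Cytosolic ribosomal proteins were also lower with PFBA as a list, with 41 of 45 fitted lower and a mean log2 fold of -0.13 (adjusted p = 8.05e-09, adjusted p = 0.420 with an estimated correlation). In that list 0 members passed over all genes and 1 was lower when adjusted over the list alone. Control d lay at 0.16 for this list, the other controls between -0.07 and -0.03, and without control d the mean log2 fold was -0.07. Collagens and other matrix genes were higher as a list, with 29 of 30 fitted higher, 0 passing over all genes, 0 adjusted over the list alone and a mean log2 fold of 0.14 (adjusted p = 3.26e-07, adjusted p = 0.420 with an estimated correlation). Here control d lay at -0.21 and the other controls between 0.02 and 0.14, and the mean was 0.07 without control d. TGF-beta and YAP target genes were higher as a list of 19 (mean log2 fold 0.13, adjusted p = 0.00271, adjusted p = 0.380 with an estimated correlation). Adjusted over the list alone, 2 were higher and 1 lower; ID3, an inhibitor of differentiation factors, was at 105.9 ± 1.80 CPM against 123.7 ± 7.00 (adjusted p = 0.256).

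A further 4 lists passed the threshold for PFBA, with 0 members called over all genes. Metallothioneins and metal response genes were higher over 6 members (mean log2 fold 0.31, adjusted p = 0.0384, adjusted p = 0.420 with an estimated correlation), with 2 higher when adjusted over the list alone; the metal-binding MT1F was at 1.53 ± 0.529 CPM against 0.632 ± 0.132 in control (adjusted p = 0.297) and MT2A at 17.3 ± 2.45 against 12.7 ± 1.12 (adjusted p = 0.304). Immediate early genes were higher over 26 members (mean log2 fold 0.10, adjusted p = 0.0457, adjusted p = 0.484 with an estimated correlation), with 1 higher when adjusted over the list alone; JUN, a subunit of the transcription factor AP-1, was at 59.6 ± 4.59 CPM against 49.0 ± 1.12 (adjusted p = 0.256). DNA replication genes were lower over 37 members (mean log2 fold -0.07, adjusted p = 0.0139, adjusted p = 0.191 with an estimated correlation) and mitosis genes over 38 (mean log2 fold -0.06, adjusted p = 0.0304, adjusted p = 0.496 with an estimated correlation). In both of these, 0 members passed when adjusted over the list alone. When 1 library was left out, immediate early genes lost the call in 6 of 12 fits (mean 0.07 to 0.17, the highest without control c; adjusted p up to 0.276), metallothioneins and metal response genes in 4 (up to 0.124), DNA replication genes in 2 (up to 0.112). Mitosis genes lost it in 3, among them the fit without PFBA d (mean -0.04, adjusted p = 0.280).

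By an unadjusted p, 1632 genes lay under 0.05 between PFBA and control. DESeq2 called 43 genes for PFBA, 23 higher and 20 lower, and limma-voom called 0. Leaving out 1 library gave 0 to 4 genes. There were 0 without control a, c or d or PFHxA a, c or d. The 1 gene lost its call in 8 of these 12 fits.

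The comparison of PFHxA with control asked what the longer acid changed. With PFHxA, 2466 of 16554 genes passed the test, 1006 of them higher and 1460 lower, with a median change of 1.20-fold. The amino acid transporter SLC7A5, of the integrated stress response by which cells adapt to lack of amino acids and to protein stress, rose from 144.6 ± 3.03 to 185.0 ± 4.52 CPM (1.28-fold, log2 fold 0.36, SE 0.0344, adjusted p = 0.00113). CPT1A, which admits long-chain fatty acids to mitochondria, rose 1.29-fold from 68.0 ± 2.32 to 87.7 ± 4.68 CPM (log2 fold 0.37, SE 0.047, adjusted p = 0.00117). HMMR, a spindle protein of dividing cells, fell by 0.64 on the log2 scale, from 28.99 ± 2.27 to 18.6 ± 1.20 CPM (SE 0.0863, adjusted p = 0.00135). The interferon-induced antiviral gene IFIT1 fell by 0.38, from 207.7 ± 17.8 to 159.9 ± 4.55 CPM (SE 0.0573, adjusted p = 0.00187).

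The changes were small and followed GC content. Of the calls, 131 were at least 1.5-fold (34 higher, 97 lower) and 17 at least 2-fold. The genes that fell had a median transcript GC content of 39.5%, those that rose 55.6%, and those not called 49.1%. Median transcript lengths were 3683, 5260 and 3069 nt, longer for called genes of either direction. Among genes under 35% GC, 35.6% were called lower, and among genes over 65% GC, 10.8% were called higher. With the trend over GC content and transcript length removed from each library, an alternative chosen after the data were seen, 433 genes were called (153 higher, 280 lower), of which 378 (106 higher, 272 lower) were also among the 2466. The 2088 genes that lost their call had a median log2 change of 0.26 before and 0.12 after, with a median SE of 0.0600 and 0.0548. Leaving out PFHxA b gave 1523 genes, the fewest of the 12 such fits, and leaving out control d gave 1784.

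Of 33 integrated stress response genes, 7 rose, 2 fell and the rest were not called, with the same counts when adjusted over the list alone (mean log2 fold 0.10, camera adjusted p = 0.00202, adjusted p = 0.290 with an estimated correlation). Beside SLC7A5, the arginine transporter SLC7A1 rose 1.23-fold to 331.2 ± 8.24 CPM, the secreted stress hormone GDF15 1.23-fold to 141.0 ± 2.71 CPM and the pseudokinase TRIB3 1.23-fold to 79.0 ± 2.30 CPM. These 4 stayed called with the GC and length trend removed. The log2 folds of SLC7A5 and SLC7A1 were then 0.22 and 0.16. Collagens and matrix genes held 13 of 30 that rose and 0 that fell, with 15 higher when adjusted over the list alone (mean log2 fold 0.21, adjusted p = 7.61e-08, adjusted p = 0.290 with an estimated correlation). The basement membrane genes HSPG2 (perlecan) and LAMA5 (a laminin chain) rose 1.46-fold, to 376.9 ± 11.3 CPM, and 1.28-fold, to 209.2 ± 6.75 CPM. With the trend removed, HSPG2, FBN1 and TIMP3 were the 3 members called. HSPG2 then had a log2 fold of 0.30 (0.54 before) and LAMA5 one of 0.12 (0.36 before). Control d lay at -0.21 for this list (other controls 0.02 to 0.14).

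TGF-beta and YAP target genes held 3 of 19 that rose and 1 that fell, with 7 higher and 1 lower when adjusted over the list alone (mean log2 fold 0.14, adjusted p = 0.00861, adjusted p = 0.290 with an estimated correlation). SMAD7, an inhibitor of TGF-beta signalling, rose 1.12-fold (adjusted p = 0.014) and CCN1, a secreted matrix protein, 1.18-fold (adjusted p = 0.0222; 0.0585 in 1 of the 12 fits without 1 library). Neither stayed called with the trend removed (adjusted p = 0.658 and 0.0759). Immediate early genes held 5 of 26 that rose, with 5 when adjusted over the list alone (mean log2 fold 0.15, adjusted p = 0.00145, adjusted p = 0.290 with an estimated correlation). JUN rose 1.31-fold to 64.3 ± 1.58 CPM and EGR1 1.26-fold to 44.99 ± 1.95 CPM. With the trend removed the list still passed (camera adjusted p = 0.0063, 0.202 with an estimated correlation), but JUN was the 1 member called and EGR1 lost its call. Basal cell genes held 5 of 20 that rose, with 5 when adjusted over the list alone, among them the receptor NOTCH1 (1.30-fold, 719.4 ± 21.5 CPM) and the laminin receptor BCAM (1.18-fold, adjusted p = 0.00482). NOTCH1 was 1.12-fold with the trend removed, and BCAM was then not called (adjusted p = 0.0776). The basal list had a mean log2 fold of 0.10 and an adjusted p of 0.0225 (adjusted p = 0.290 with an estimated correlation), which became 0.357 with the trend removed, 0.0806 without control d (mean 0.07) and 0.0516 without PFHxA a. Lysosome and autophagy genes held 6 of 29 that rose, with 8 higher and 1 lower when adjusted over the list alone; PSAP, a precursor of lysosomal activator proteins, rose 1.13-fold. That list had a mean log2 fold of 0.04 and an adjusted p of 0.0183 (adjusted p = 0.290 with an estimated correlation), 0.0650 with the trend removed, and a mean of 0.03 without control d. With the trend removed, 0 of these 6 genes stayed called, and PSAP lost its call as well.

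Mitosis genes held 13 of 38 that fell and 1 that rose, with 13 lower and 2 higher when adjusted over the list alone (mean log2 fold -0.18, adjusted p = 0.000188, adjusted p = 0.290 with an estimated correlation). The spindle gene ASPM went from 69.7 ± 5.75 to 49.7 ± 6.16 CPM, DLGAP5 from 54.5 ± 1.03 to 38.2 ± 4.19 CPM and the cytokinesis regulator ECT2 from 70.6 ± 2.82 to 54.0 ± 2.57 CPM. With the trend removed, 6 stayed called, HMMR, ASPM, DLGAP5, ECT2, CENPE and CENPF. The log2 folds were then -0.40 for HMMR (-0.64 before), -0.30 for DLGAP5 (-0.51) and -0.21 for ECT2 (-0.39). Interferon-stimulated genes held 8 of 33 that fell and 1 that rose, with 9 lower and 1 higher when adjusted over the list alone (mean log2 fold -0.14, adjusted p = 0.0183, adjusted p = 0.290 with an estimated correlation). IFIT2 went from 47.9 ± 2.15 to 38.7 ± 2.12 CPM and IFIT3 from 47.0 ± 2.07 to 39.3 ± 0.727 CPM; IFIT1, IFIT3, DDX60 and SAMD9 stayed called with the trend removed, IFIT3 with a log2 fold of -0.17 (-0.25 before).

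The 2 genomes that encode the respiratory chain differed in direction with PFHxA. Of 13 mitochondrially encoded genes, 8 rose, with 10 when adjusted over the list alone (mean log2 fold 0.28, adjusted p = 1.85e-05, adjusted p = 0.457 with an estimated correlation); MT-ND4 rose 1.28-fold from 9806 ± 1545 to 12550 ± 736.1 CPM (adjusted p = 0.0243). The mitochondrial share of all counts was 12.6% in these libraries and 10.9% in control, and MT-ND4 lost its call without PFHxA b, c or d (adjusted p = 0.0619, 0.0551 and 0.0585). With the trend removed, MT-ND4 was the 1 of the 13 called, and the list still passed (camera adjusted p = 3.63e-11, 0.202 with an estimated correlation). Control d lay at -0.36 for the mitochondrially encoded list and the other controls between 0.05 and 0.16, and the mean log2 fold was 0.17 without control d. Of 56 nuclear-encoded oxidative phosphorylation genes, 10 fell and 0 rose, with 12 lower when adjusted over the list alone (mean log2 fold -0.15, adjusted p = 4.72e-05, adjusted p = 0.457 with an estimated correlation). ATP5PB went from 221.1 ± 16.4 to 168.1 ± 16.6 CPM and COX7B from 151.1 ± 13.2 to 117.1 ± 4.75 CPM (call lost in 1 fit without 1 library, adjusted p = 0.0532), and NDUFS3 was the 1 member still called with the trend removed. Cytosolic ribosomal proteins held 8 of 45 that fell, with 11 lower when adjusted over the list alone and all 45 fitted lower (mean log2 fold -0.17, adjusted p = 5.11e-06, adjusted p = 0.457 with an estimated correlation); RPL26 went from 880.4 ± 55.1 to 697.4 ± 44.6 CPM. With the trend removed, 0 of the 45 ribosomal genes were called, although the list still passed (camera adjusted p = 1.08e-08, 0.202 with an estimated correlation). Control d was the highest control for the oxidative phosphorylation and ribosomal lists, at 0.13 and 0.16, and without control d the mean for ribosomal proteins was -0.11.

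Several lists did not pass as a whole but held called members. Of all tested genes 14.9% were called, and counts near that share do not set a list apart. Of 20 heat shock genes 7 fell and 1 rose (adjusted p = 0.0793), and the chaperone HSP90AA1 went from 1485 ± 64.7 to 1129 ± 89.3 CPM. The heat shock list passed with the trend removed (adjusted p = 0.0133, 0.202 with an estimated correlation) with 2 lower and 0 higher. Of 18 fatty acid synthesis and LXR target genes 6 rose and 1 fell (adjusted p = 0.0602), with the lipid regulator SREBF1 up 1.22-fold and the synthase FASN up 1.16-fold to 603.1 ± 14.4 CPM. The log2 folds were 0.14 for SREBF1 (0.29 before; adjusted p = 0.153) and -0.01 for FASN with the trend removed. Mesenchymal genes of the epithelial-mesenchymal transition held 4 of 21 that rose (adjusted p = 0.0745), among them fibronectin, FN1, 1.24-fold, and the cadherin CDH11, 1.17-fold. This list passed with the trend removed (adjusted p = 0.0273, 0.202 with an estimated correlation, 3 higher). PPAR alpha target genes, which fatty acids and compounds that resemble them induce, held 1 of 22 that rose, CPT1A, and 3 that fell (adjusted p = 0.790). The 3 were ACADM and HADHB of mitochondrial fatty acid oxidation and the acyl-CoA ligase ACSL3, at 76.3 ± 8.16, 200.4 ± 10.7 and 76.8 ± 3.89 CPM. They lost their calls with the trend removed (adjusted p = 0.17, 0.309 and 0.253). In that setting 3 of the list were higher and 0 lower. Cholesterol genes held 2 of 27 that rose and 3 that fell (adjusted p = 0.452), NRF2 target genes 3 of 28 and 1 (adjusted p = 0.452), hypoxia and glycolysis genes 1 of 35 and 4 (adjusted p = 0.592, and 0.0120 with the trend removed, 0.202 with an estimated correlation as well), p53 target genes 2 of 26 and 3 (adjusted p = 0.790), DNA replication genes 3 of 37 and 4 (adjusted p = 0.790) and the unfolded protein response 0 of 22 and 3 (adjusted p = 0.386). Adjusted over the list alone, the counts were the same for heat shock, fatty acid synthesis, PPAR alpha, hypoxia, p53, DNA replication and unfolded protein response genes, 2 and 5 for cholesterol genes, 4 and 1 for NRF2 targets and 5 and 0 for mesenchymal genes.

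Beside the basal cell list, airway cell types held few called genes with PFHxA. Motile ciliated cell genes held 0 of 21 called, mucins and secretory products 1 of 13 higher, ion and water transport 1 of 14 higher, desmosomes and squamous keratinization 1 of 14 higher, and tight and adherens junctions 2 of 27 higher and 1 lower. Markers of endothelial cells held 0 of 7 called, and too few markers of immune cells (4), fibroblasts (3) and neurons (4) were expressed to be tested as lists; none of these was called. Adjusted over the list alone, 2 secretory genes were higher and 1 lower, 1 transport gene was higher, 2 junction genes were higher and 1 lower, and 0 were called among ciliated, desmosome and endothelial genes.

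**Figure D2:**
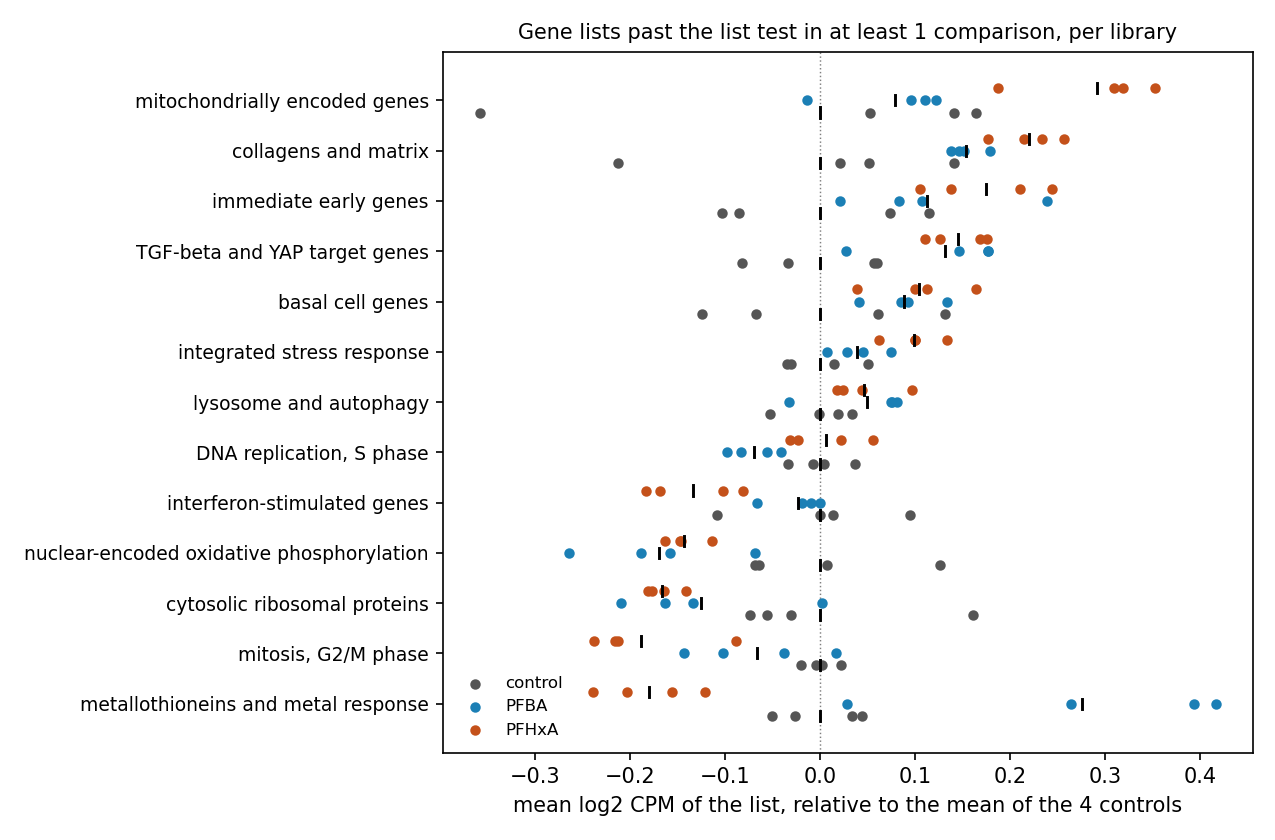
Mean log2 CPM of the members of 13 gene lists in each library, relative to the mean of the 4 controls, with 1 point per library coloured by group and a short bar for the group mean. The PFHxA libraries average 0.29 for mitochondrially encoded genes and -0.19 for mitosis genes, and the PFBA libraries -0.17 for nuclear-encoded oxidative phosphorylation genes.

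By size of change, among the largest rises with PFHxA under the rule for named genes, the transcriptional coactivator MRTFB rose 1.81-fold to 103.5 ± 3.59 CPM, although it lost its call in 9 of the 12 fits without 1 library (adjusted p up to 0.0966). PAX8-AS1, an antisense transcript, rose 1.79-fold to 17.2 ± 2.16 CPM and AVL9 1.62-fold to 137.4 ± 1.94 CPM. DEGS1, which makes ceramide, rose 1.61-fold to 41.6 ± 8.42 CPM, and AHR, the aryl hydrocarbon receptor, 1.59-fold to 3.09 ± 0.346 CPM. SYNE3, LY6G5C, FRMD5 and MYO10 were also among these rises. When 1 library was left out, FRMD5 lost its call in 11 of 12 fits (adjusted p up to 0.123), DEGS1 in 6 (0.0678) and AHR in 5 (0.0820). PAX8-AS1, LY6G5C, AVL9, DEGS1 and AHR also stayed called with the trend removed. MRTFB and FRMD5 did not, although their log2 folds were about as large (0.81 and 0.74, before 0.85 and 0.69; adjusted p = 0.127 and 0.0874).

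Of the named genes FRS2, an adaptor of the FGF receptors, fell most, by 1.52 on the log2 scale, from 56.6 ± 1.20 to 19.8 ± 0.857 CPM (SE 0.243, adjusted p = 0.0037). FRS2 was also at 22.6 CPM in PFBA d, with the other PFBA libraries between 55.5 and 57.1 CPM, and it is 1 of 69 genes whose 12 libraries lie at a pair of separate levels. CENPE, a kinetochore motor, fell by 1.01 (SE 0.179, adjusted p = 0.00469), from 35.5 ± 4.17 to 17.7 ± 5.80 CPM. The others were S100A14, C7orf25, OMD, LINC00706, PDC, SCEL, ZNF17 and MNS1, with log2 folds from -1.36 to -0.92, and FRS2, CENPE, ZNF17 and MNS1 stayed called with the trend removed. S100A14 and C7orf25 did not, at log2 folds of -1.36 and -1.08 (before -1.36 and -1.19; adjusted p = 0.0541 and 0.127). C7orf25 lost its call in 8 of the 12 fits without 1 library (adjusted p up to 0.104), SCEL in 4 (0.0944) and S100A14 in 2 (0.0582).

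**Figure D3:**
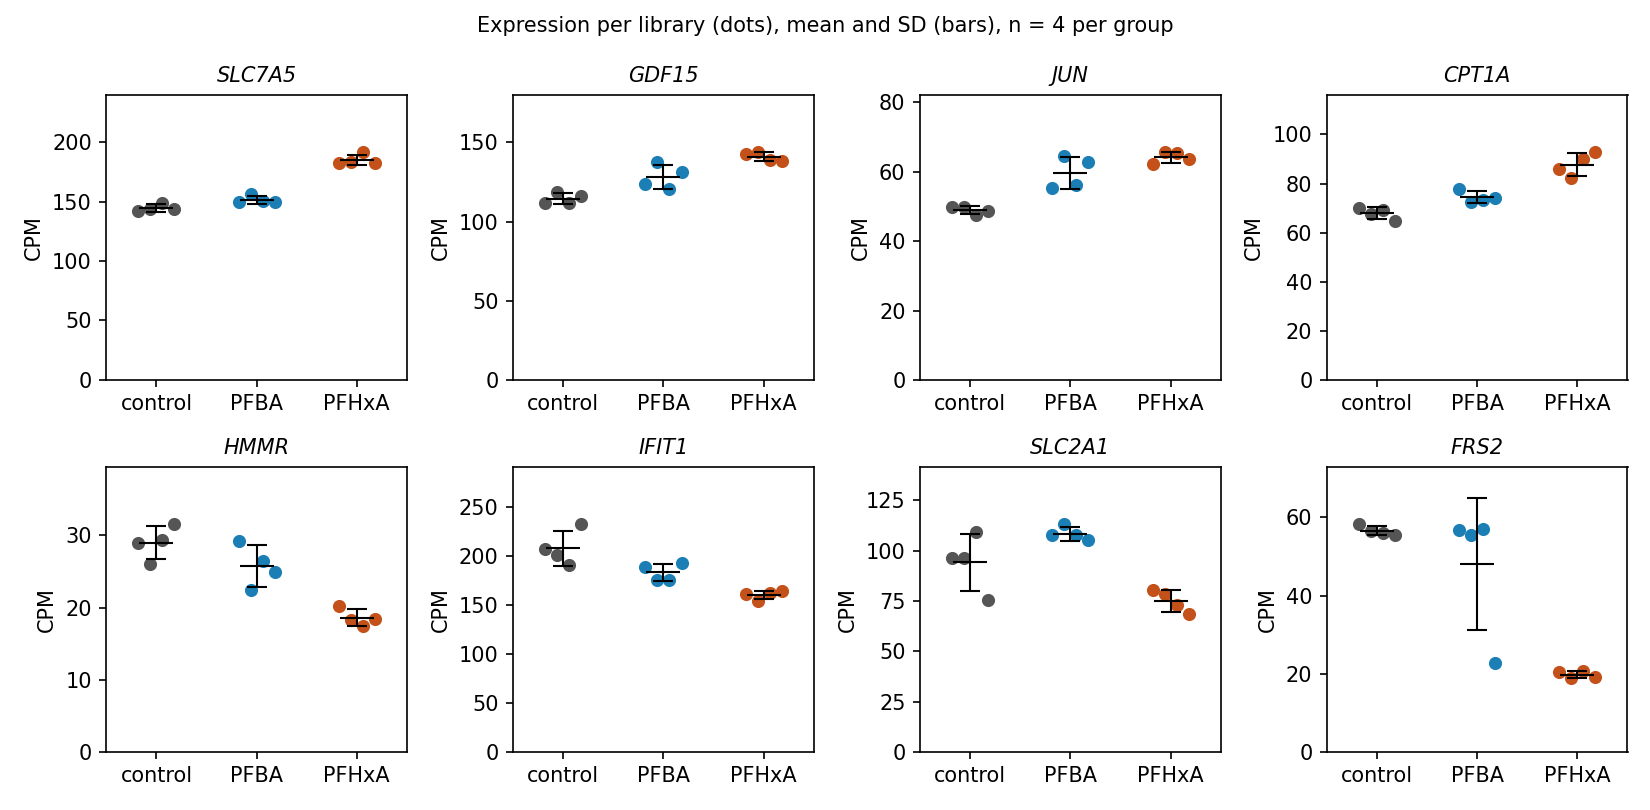
CPM of 8 genes in each library (points) with the group mean and SD, by group. SLC7A5 averages 185.0 CPM with PFHxA and 144.6 in control, and HMMR 18.6 and 28.99.

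The direct comparison of PFHxA with PFBA tested whether libraries of acids of different chain length differ at the same dose of 1 µM and the same 7 days. Between them 1806 genes passed, 636 higher with PFHxA and 1170 lower. With the GC and length trend removed, 125 of these stayed called. SLC7A5 was higher with PFHxA than with PFBA by 0.29 on the log2 scale (95% interval 0.21 to 0.36, adjusted p = 0.00116), CPT1A by 0.24 (0.13 to 0.34, adjusted p = 0.00729) and FASN by 0.31 (0.22 to 0.41, adjusted p = 0.00182). The glucose transporter SLC2A1 was at 75.0 ± 5.44 CPM with PFHxA and 108.4 ± 3.41 with PFBA (log2 difference -0.53, interval -0.73 to -0.33, adjusted p = 0.00372), and HSP90AA1 differed by -0.30 (-0.42 to -0.19, adjusted p = 0.00412). MT1F was lower with PFHxA by 3.85-fold, at 0.393 ± 0.144 against 1.53 ± 0.529 CPM (log2 difference -1.94, SE 0.314, adjusted p = 0.00278). These levels are low, and MT1F was not called against control with PFBA (adjusted p = 0.297) or with PFHxA (adjusted p = 0.24).

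For other genes a difference between the acids was not detected, which does not show that they act alike. JUN differed by 0.11 (95% interval -0.01 to 0.22, adjusted p = 0.212), GDF15 by 0.14 (0.04 to 0.24, adjusted p = 0.0652) and AHR by -0.15 (-0.53 to 0.24, adjusted p = 0.660). AHR had a log2 fold of 0.82 with PFBA against control (SE 0.187, adjusted p = 0.297) beside 0.67 with PFHxA. Of the 2466 genes called for PFHxA against control, 1159 (47.0%) were not called against PFBA. In both comparisons 399 were higher with PFHxA and 908 lower, where 38.7 and 103 would be shared if the calls were independent, which they are not because the same PFHxA libraries enter both.

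By list, 3 of 38 differed between the acids. There were 7 with the trend removed, none of them with an estimated correlation (adjusted p = 0.193 to 0.686). Collagens lost the call (adjusted p = 0.515), and cholesterol, fatty acid synthesis, heat shock, hypoxia and glycolysis and nuclear-encoded oxidative phosphorylation genes gained it (adjusted p = 0.00625, 0.0105, 0.00948, 0.0141 and 0.0126). Metallothioneins and metal response genes were lower with PFHxA, with 3 of 6 lower and 3 when adjusted over the list alone. The mean log2 difference was -0.50 (adjusted p = 0.0138, adjusted p = 0.564 with an estimated correlation) and the median -0.21, as MT1F weighs heavily in the mean. The 3 were MT1F and the zinc transporters SLC39A10 and SLC30A1. With the trend removed MT1F alone stayed called. SLC39A10 then had an adjusted p of 0.123 and SLC30A1 a log2 difference of 0.07. SLC30A1 also lost its call in 7 of the 12 fits without 1 library (adjusted p up to 0.122). Mitochondrially encoded genes were higher by a mean of 0.21, with 0 of 13 called and 10 when adjusted over the list alone (adjusted p = 0.00317, adjusted p = 0.685 with an estimated correlation), beside mitochondrial shares of 12.6% and 11.4%. Collagens and matrix genes were higher by 0.07, with 5 of 30 called and 7 when adjusted over the list alone (adjusted p = 0.0150, adjusted p = 0.685 with an estimated correlation), and the mean was -0.01 with the trend removed. Mitosis genes, with 12 of 38 lower and 1 higher, had an adjusted p of 0.0617 as a list. Integrated stress response genes, with 5 of 33 higher and 2 lower, also had 0.0617. Adjusted over the list alone, 12 were lower and 4 higher and 9 were higher and 2 lower. With the trend removed the camera adjusted p was 0.396 for mitosis genes (3 lower, 0 higher) and 0.528 for integrated stress response genes (1 higher, 0 lower). Nuclear-encoded oxidative phosphorylation genes held 3 of 56 higher with PFHxA than with PFBA, 1 adjusted over the list alone (mean log2 difference 0.03, adjusted p = 0.229). This list was lower with PFBA and with PFHxA against the same 4 controls. Neither call held with an estimated correlation (camera adjusted p = 0.191 and 0.457). PPAR alpha target genes held 1 of 22 higher and 4 lower (adjusted p = 0.833), 1 and 0 with the trend removed, with a mean of -0.04 here and means of 0.10 and 0.06 for PFBA and PFHxA against control.

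The largest rises under the rule were in the heparan sulfate enzyme NDST1 (log2 difference 1.04, SE 0.278, adjusted p = 0.0416), the muscle form of carnitine palmitoyltransferase CPT1B (0.97, SE 0.272, adjusted p = 0.0364) and CASP2 (0.89, SE 0.195, adjusted p = 0.0153). NDST1 had 1 control library at 113.3 CPM and 1 PFHxA library at 70.3 CPM, and it lost its call in 8 of the 12 fits without 1 library (adjusted p up to 0.112), CPT1B in 6 (0.0968). Smaller rises were in LY6G5C, LTB4R2, LINC02604, ZBTB11-AS1, DMWD, CLPTM1 and WRNIP1. LTB4R2 lost its call in 7 such fits (adjusted p up to 0.107), LINC02604 in 6 (0.0633) and ZBTB11-AS1 in 6 (0.0947). The largest falls were in RPL36A-HNRNPH2, a readthrough locus that overlaps RPL36A and HNRNPH2 (log2 difference -1.45, SE 0.265, adjusted p = 0.0072), OMD (-1.34), FRS2 (-1.28), HOOK1 (-0.99; call lost in 8 fits, adjusted p up to 0.145) and CENPE (-0.99). ZNF17, the centrosomal scaffold AKAP9 (79.1 ± 22.3 against 150.8 ± 7.16 CPM), ESF1, the kinesin KIF20B and the ciliary gene CEP290 followed, with log2 differences of -0.94 to -0.87. The apoptosis inhibitor XIAP was lower with PFHxA than with PFBA by 1.74 on the log2 scale, at 15.6 ± 0.890 against 52.2 ± 28.1 CPM (adjusted p = 0.021), but its libraries overlapped between the groups. Against control, its log2 fold was -0.02 with PFHxA (adjusted p = 0.985) and 1.73 with PFBA (adjusted p = 0.304). XIAP lost its call in 5 fits (adjusted p up to 0.0615).

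Genes lower with PFHxA than with PFBA had a median GC content of 38.9%, those higher 58.4% and those not called 49.0%. With the GC and length trend removed, 146 genes were called (37 higher, 109 lower), of which 125 were among the 1806, SLC7A5, FASN, SLC2A1, HSP90AA1, MT1F, CENPE and CEP290 among them; CPT1A was not. The log2 difference was then 0.17 for SLC7A5 (0.29 before) and 0.16 for FASN (0.31 before). Leaving out 1 library gave 1035 genes without PFHxA b, 1108 without PFBA d, 1143 without PFBA c, 1151 without PFBA a, 1179 without PFHxA c and 2187 without control d.

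**Figure D4:**
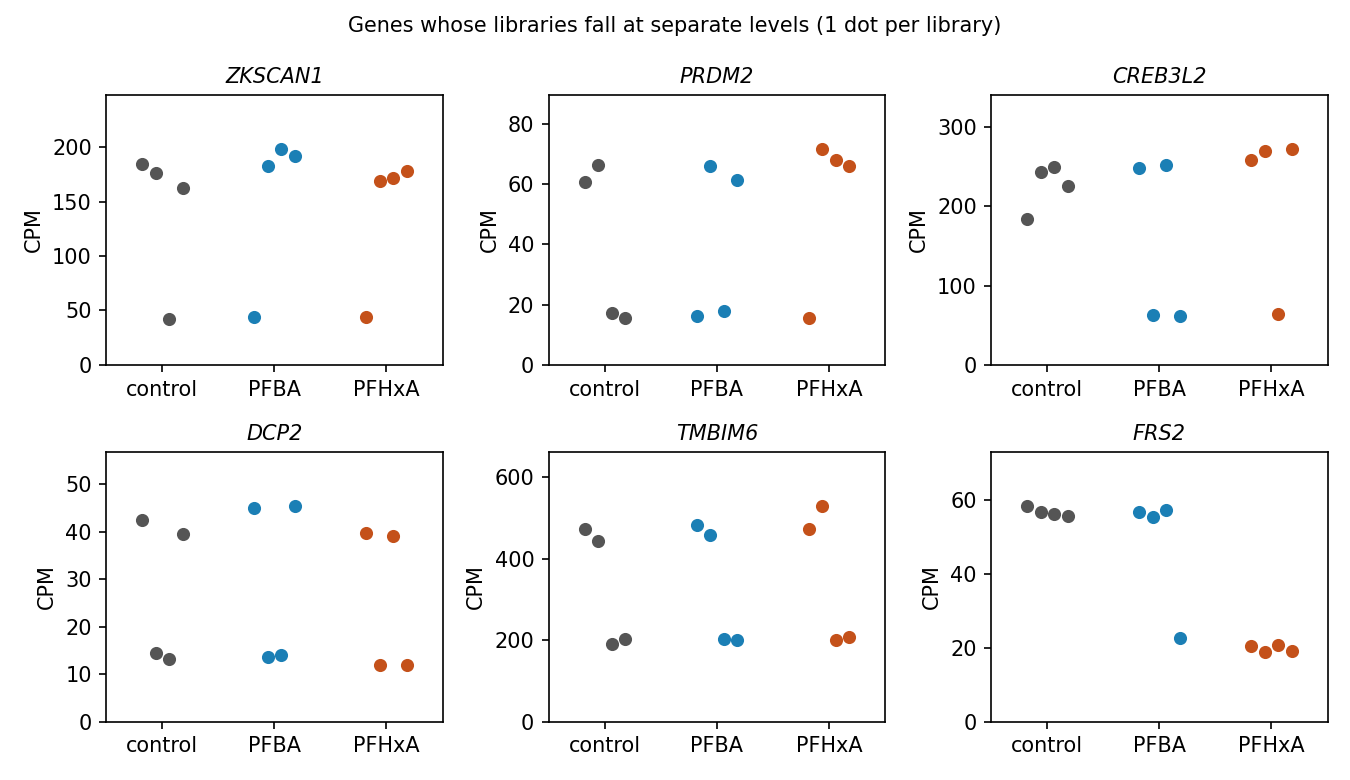
CPM in each of the 12 libraries by group for 6 genes, chosen after their values were seen, whose libraries lie at a pair of separate levels. ZKSCAN1 averages 43.3 CPM in its low libraries and 179.5 in the others, and the sets of low libraries differ from gene to gene.

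Both acids were compared with the same 4 controls, which by itself makes their fold changes alike. Across genes of at least 1 CPM, the log2 fold changes for PFBA and for PFHxA had a Pearson correlation of 0.511, where simulated data with no change in any group gave 0.501 (0.420 to 0.550 over 20 draws) and a split of the controls into 2 and 2 libraries gave 0.0418 (-0.00605 to 0.126 over 6 assignments). The simulated tables left PFHxA unchanged, unlike the data, and a change with PFHxA alone lowers a correlation. The near match of 0.511 and 0.501 therefore does not show that no response is shared. The covariance was 0.0290, above all 20 simulated draws (mean 0.0179, 0.0139 to 0.0215). With split controls it was 0.00414 (-0.000661 to 0.0120), so that a shared response is neither shown nor excluded. These values are across genes, which are not independent replicates. Higher with both acids was 1 gene, with 0.0672 expected among these genes if the calls were independent, and 0 genes were lower with both. Controls shared by both comparisons enter that overlap as well.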

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

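The tests of oxidative phosphorylation genes were chosen after the result was seen, as were the removal of the GC and length trend, the thinning of libraries and the count by column letter, and the pattern of genes at separate levels was noticed in the data before it was tested.

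In 17 of 132 sets of 4 libraries, covering the library measures and the CPM of the genes with the largest calls, 1 library lay far from the other 3 (gap to the nearest over the whole range, above Dixon's critical value at 95%); chance gives about 1 in 20, or 6.6. The mitochondrial share was 11.7% in PFHxA a (95% Wilson interval 11.69 to 11.72) and 12.7% to 12.9% in the other PFHxA libraries. The TMM factor was 1.0078 in PFBA b and 1.00415 to 1.00447 in the others. PAX8-AS1 was at 17.7 CPM in PFBA d (others 12.5 to 12.9) and at 13.99 CPM in PFHxA d (18.1 to 18.4). DEGS1 was at 28.9 CPM in PFHxA d (45.5 to 46.2), FRS2 at 22.6 CPM in PFBA d (55.5 to 57.1) and LINC00706 at 1.78 CPM in PFBA d (1.13 to 1.18). PFHxA a stood out at 26.3 CPM for CENPE (14.3 to 15.1), 112.2 CPM for AKAP9 (63.2 to 70.9), 66.4 CPM for KIF20B (41.0 to 42.5) and 70.3 CPM for NDST1 (137 to 146.4). NDST1 was also at 113.3 CPM in control d (57.1 to 66.2). CASP2 was at 35.03 CPM in control a (26.7 to 27.9), DMWD at 33.0 CPM in control b (23.3 to 24.8) and CLPTM1 at 139.2 CPM in control d (112.4 to 116.2). WRNIP1 was at 106.9 CPM in PFHxA d (131.3 to 134) and RPL36A-HNRNPH2 at 10.1 CPM in PFBA b (25.9 to 27.4).

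The genes called for PFHxA follow GC content, and with each library's trend over GC content and length removed 15.3% of the 2466 stayed called and the median log2 change went from 0.27 to 0.14 (median SE 0.0601 and 0.0541), so that a bias of the libraries may account for a large part of the typical change and for most calls; of the 2088 genes that lost their call, the fold of 1626 (77.9%) became over 1.5 times smaller or turned sign, and the others lost it with less change. A difference in library size is argued against by the totals themselves. Those of the PFHxA libraries (18051645 to 20405688) lay within the range of the controls (16941599 to 21508681; exact permutation p = 0.886). In thinned libraries 89.5% stayed called, but with totals this close thinning could hardly have removed most calls, so that it adds little. Among long noncoding genes the slope was 0.0620 per 10 points of GC (95% interval 0.0435 to 0.0806). By the rule used, an interval above 0 argued against regulation limited to protein-coding messages as the whole source. That interval is across genes, not libraries. For PFBA against control it also left out 0 (-0.0422 to -0.00856), although the GC slopes of those libraries were not separated (exact permutation p = 0.914). The rule therefore cannot decide, and no conclusion is drawn from it. The slope was steeper among protein-coding genes, 0.122 (0.117 to 0.127), so that regulation of these messages is not excluded. The 433 genes called with the trend removed were selected by that removal, so that their calls do not test the trend as a source. Of them 87.5% stayed called when the GC of stretches within the transcript was removed as well, so that these stretches alone do not account for most of the 433. Of 35 splits of the 8 libraries 1, the real one, gave as many genes (highest other 3). Neither result separates a leftover bias from exposure, because all 4 PFHxA libraries share the trend. Whether the trend itself comes from library preparation or from an effect of PFHxA on GC-poor and GC-rich messages stays open, because all 4 PFHxA libraries and no others carry it and no batch is given.

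Nuclear-encoded oxidative phosphorylation genes had a mean log2 difference of -0.170 between PFBA and control (95% Welch interval -0.320 to -0.0204); all 4 PFBA libraries lay below all 4 controls (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.418 over 38 lists), but PFBA d and control a were both at -0.07. With the GC and length trend removed the difference was -0.143 (interval -0.257 to -0.02997; camera adjusted p = 7.1e-17, 0.168 with an estimated correlation), so that the trend is argued against as the whole source. Without control d, which differs from the other controls in mitochondrial share, it was -0.128 (interval -0.252 to -0.00364). By the rule used this too argued against control d as the whole source, but only just. The interval ended near 0, and the lowest control and highest PFBA library were 6.62e-05 apart on the log2 scale. No conclusion is therefore drawn on control d. A part may come from either, since neither interval leaves out -0.0425, the bound first set for a pattern made by them. The rule for this was changed 3 times after both differences were seen: by the differences alone, and by intervals that leave out 0 as used here, both are argued against, by intervals that leave out -0.0425 neither, and by a margin of 2 SE from it the trend alone (2.25 SE, and 1.80 for control d). An effect of PFBA and an unrecorded difference between the preparations of the libraries stay open, and chance is not excluded, because 2 of 35 splits called as many lists as the real one (8, highest other 8).

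For 69 of 10061 genes at a mean of at least 10 CPM, the 12 libraries lie at separate levels with a gap of at least 0.8 on the log2 scale, an SD of at most 0.2 on each side and at least 2 libraries per side; spread of the size the fit estimates is argued against, since 20 simulated tables held at most 1 such gene (mean 0.1). Examples, chosen after their values were seen, are PRDM2 (16.5 CPM in 5 libraries, 65.8 in the others), CREB3L2 (63.3 in 3, 245.1), TMBIM6 (201.1 in 6, 476.8) and DCP2 (13.2 in 6, 42.0). The levels follow the groups exactly in 0 of the 69 and the column letters in 2 (TMBIM6 and CTDSPL; 0.366 expected for random sets), and FRS2 is the 1 that separates PFHxA from control, with 0.199 expected for random sets of libraries. Of these genes 34.8% overlap another gene on the same strand, against 23.1% of all genes at that level, so that reads shared with an overlapping gene may be the source for some and cannot be told apart from other sources, since the program that assigned the reads is not given. No biological explanation was tested, and the fold of FRS2 rests on this pattern.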

How the results depend on the processing

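The removal of the GC and length trend, the letter block and the thinning of libraries were chosen after the data were seen, and the other alternatives before. The planned block by label number was not run, since the columns carry letters. A replicate block by column letter gave 0 genes for PFBA, 2441 for PFHxA and 1838 for the difference, and 9, 11 and 4 lists; 230 of 242 named results and all 22 lists kept their call. The letters do not pair the libraries (correlation of deviations -0.0896 to 0.0625 in 12 pairs of the same letter, and 0 libraries closest to their own letter in both other groups). For counts, the alternatives for normalized values were not run. At least 1.5-fold, 131 genes were called for PFHxA against control and 92 against PFBA, by construction of the threshold. With an estimated correlation, 0, 0 and 0 lists were called for PFBA, for PFHxA and for the difference. For PFBA against control, 2 genes were called with no filter, 2 (both lower, the 1 gene no longer among them) in a fit of the 8 libraries, 0 with limma-voom (1720 genes under an unadjusted p of 0.05) and 43 with DESeq2; the cause was not tested. With the trend removed, 433 genes were called for PFHxA against control, 146 against PFBA, and 11, 12 and 7 lists: 3 gained for PFBA, heat shock, hypoxia and mesenchymal genes gained and basal and lysosome genes lost for PFHxA. In that setting 88 of the 2466 genes called for PFHxA and 85 of the 1806 called for the difference turned sign; among named genes and lists these were STARD4 to 0.0383 and FASN to -0.0061 on the log2 scale for PFHxA against control, SLC30A1 to 0.0653 for PFHxA against PFBA, and the mean log2 fold of the list collagens and matrix, PFHxA against PFBA, to -0.00755. The correlation of the acids' fold changes was 0.0418 with the controls split, since the 2 sets share no control. Leaving out 1 library gave 0 to 4 genes for PFBA, 1523 to 2396 for PFHxA and 1035 to 2187 for the difference, 5 to 10, 10 to 12 and 3 to 6 lists, with the lowest gene counts without control a, c or d or PFHxA a, c or d (PFBA, 0) and without PFHxA b (1523 and 1035). No named gene turned sign when 1 library was left out. Of 242 results for named genes, 73 kept their direction and side of the threshold in every alternative that gave them a result. Thinning was run for PFHxA against control alone, and DESeq2 gave no adjusted p for some of the 242. With the trend removed 87 kept both, 152 were no longer called and 3 turned sign. In simulated data of this design 50% of 1.5-fold changes were recovered, so that changes of this size or smaller may be missed. Whether the 43 genes called by DESeq2 for PFBA are such changes was not tested.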

Other observations

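The splits of libraries were planned before their results were seen. Further lists that did not pass for PFHxA against control held called members, beside a share of 14.9% called among all tested genes. Among carriers of organic anions, fatty acids and perfluoroalkyl acids, 3 of 16 rose and 2 fell (adjusted p = 0.807; 3 and 3 when adjusted over the list alone). The organic anion transporter SLCO1A2 went from 24.8 ± 0.369 to 19.4 ± 0.991 CPM (n = 4, edgeR adjusted p = 0.00199) and the fatty acid binding protein FABP5 from 59.2 ± 2.46 to 50.4 ± 2.10 CPM, while the efflux pump ABCC1 rose 1.17-fold. Of 31 NF-kB inflammatory genes 3 rose and 1 fell (adjusted p = 0.373; 3 and 1 over the list alone): the chemokine CCL20 went from 16.5 ± 0.647 to 10.9 ± 1.42 CPM, and its pathway inhibitor TNFAIP3 rose 1.398-fold to 2.86 ± 0.128 CPM (adjusted p up to 0.0517 in 1 fit without 1 library). Of 27 apoptosis regulators 2 rose and 1 fell (adjusted p = 0.790; 2 and 1 over the list alone). The death receptor FAS of the p53 list went from 26.8 ± 1.77 to 18.3 ± 1.66 CPM. Of 15 WNT and NOTCH target genes 2 rose (adjusted p = 0.235; 2 over the list alone), NOTCH3 by 1.32-fold to 93.6 ± 4.08 CPM. Of 10 estrogen and thyroid receptor targets 2 rose (adjusted p = 0.531; 2 over the list alone), GREB1 by 1.19-fold. Of these genes SLCO1A2 and NOTCH3 stayed called with the GC and length trend removed, NOTCH3 at a log2 fold of 0.19 (0.40 before). The others did not: ABCC1 at 0.08 (0.23 before, adjusted p = 0.283), CCL20 at -0.27 (-0.60, 0.108), FAS at -0.34 (-0.55, 0.0901), GREB1 at 0.09 (0.26, 0.381), FABP5 at -0.17 (-0.23, 0.059) and TNFAIP3 at 0.42 (0.48, 0.104).

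The remaining lists held few called genes with PFHxA. AHR, CAR and PXR targets held 1 of 8 higher (adjusted p = 0.787), MHC genes 1 of 18 higher (adjusted p = 0.592), alarmins 0 of 6, replication-dependent histones 0 of 23 and small nuclear and related RNAs 0 of 5, the last with a mean log2 fold of -0.30, and metallothioneins 1 of 6 lower (mean -0.19, adjusted p = 0.203). With PFBA, 30 lists were not called; PPAR alpha targets had an adjusted p of 0.207, the integrated stress response 0.118, basal cell genes 0.0541 and mitochondrially encoded genes 0.118. With the trend removed the integrated stress response (adjusted p = 0.00677), mitochondrially encoded genes (0.00465) and lysosome genes (0.0304) were called for PFBA, and none of them with an estimated correlation (0.213, 0.633 and 0.194). The sign of the camera test differed from that of the list mean for some lists, none of them called: with PFBA for cholesterol, NRF2, unfolded protein response, alarmin, ciliated and carrier genes, with PFHxA for MHC genes, apoptosis regulators and WNT and NOTCH targets, and between the acids for AHR, CAR and PXR targets, NF-kB, ciliated, lysosome, carrier, WNT and NOTCH and hormone receptor genes.

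Other splits of the 8 libraries of each comparison were fitted in the same way, 35 in each. For PFHxA against control, 1 split, the real one, gave as many as 2466 genes (highest other 3), and 1 gave as many as 11 lists (highest other 9). A share of 1 in 35 is the smallest that these splits allow. The margin was wide for genes and narrow for lists, and 0 lists were called with an estimated correlation. Splits cannot tell an effect of exposure from a difference between the cultures or preparations of the groups. For PFHxA against PFBA, 1 split gave as many as 1806 genes (highest other 4), while 5 gave as many as 3 lists (highest other 5), so that chance is not excluded for these lists. For PFBA against control, 16 splits gave as many as 1 gene (highest other 3) and 2 as many as 8 lists (highest other 8), so that chance is not excluded for either. The single gene and the lists called for PFBA may therefore arise from the grouping alone (16 and 2 of 35 splits).

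A hypothesis for follow-up is that PFHxA lowers mitotic transcripts and raises amino acid transport genes beyond the GC trend: 378 of the 2466 genes stayed called with the trend removed (15.3%). HMMR (log2 fold -0.64, and -0.40 with the trend removed), ASPM (-0.49 and -0.37), SLC7A5 (0.36 and 0.22) and SLC7A1 (0.30 and 0.16) are among them with smaller folds, and that set may hold effects of exposure. These values are against control. Against PFBA with the trend removed, ASPM and SLC7A5 stayed called, and HMMR and SLC7A1 did not. The mitosis and integrated stress response lists then had camera adjusted p of 0.396 and 0.528. A test of the hypothesis would be new libraries of separate cultures prepared in an order mixed across groups, with the GC slope of each library measured before the groups are compared. For genes at separate levels (69 here), counting the same reads again with a stated annotation and strand setting would show whether the levels lie in the alignments.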
